A study of Mus musculus with 6 samples.

How the data were processed

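RNA was measured by single-end 75 bp sequencing in 6 libraries of brain ILC2 cultured for 2 weeks, 3 from mice of 2 to 3 months (young) and 3 from mice of 20 to 22 months (aged), grouped by the age in their titles. Per the labels' protocols, ILC2 were sorted from brain by surface markers, cultured with 20% fetal calf serum and IL-7, IL-2, IL-33 and stem cell factor, and total RNA was extracted with Trizol-LS before Illumina library preparation. The authors deposited a single table of raw gene counts, whole numbers per gene symbol and library, without normalization. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC 1.0.0, STAR 2.5.3a, Cufflinks 2.0, DESeq2 1.1 and the build mm10. Which tool counted the reads, the gene annotation and the strand setting are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads shared with paralogs or processed copies may have been split or dropped. Among the genes that the rule below names and that are reported here, these share at least 10% of their exon length with another annotated gene, which leaves their counts uncertain: Jund, Tnfrsf18, Il5, Fdps, Ifng, Ube2c, Bnip3, B3gnt8, Penk, Cox5a and Csf2.

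The table holds 24421 rows, and library totals ran from 16477157 to 20804291 counts. Symbols of 27 rows had been turned into calendar dates, among them 2 names that occur more than a single time. These rows, 0.153% of all counts, stayed in library sizes and tests and are never named. No row starts with mt-, so a mitochondrial share could not be computed. Symbols were matched to GENCODE vM21 (GRCm38, the assembly called mm10) for coordinates, transcript length and GC content, and 98.3% of symbols had a transcript length. Older symbols were matched through a RefSeq table of GRCm38.p6. The list members Trac, Trbc2, Ighm, Igkc, Ncr2 and Ly6g were not analysed here.

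Counts were analysed in R 4.3.3 with edgeR 4.0.16, keeping genes that passed filterByExpr (minimum count 10, minimum total 15), which left 11805 genes (48.3%). Libraries were scaled by TMM, with factors of 1.16 ± 0.030 in young and 0.865 ± 0.023 in aged libraries (SD, n = 3 each), and aged was compared with young by glmQLFit and glmQLFTest. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The standard error of a log2 change is its size divided by the root of the F statistic. CPM values are computed from TMM-scaled library sizes unless library totals are named. A gene with 0 counts in a group is given a floor of 3 counts over that group, 0.0474 CPM in young and 0.0657 CPM in aged, which covers counting error only. The common biological coefficient of variation was 53%, at 47.2% within young and 58.8% within aged libraries. The first principal component of log2 CPM separated the groups and held 46.6% of the variance. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 35.7 to 89.2, against 178.9 to 333.6 between groups, which does not tell separate animals from separate preparations of a culture.

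Gene lists were tested with limma 3.58.1 (camera) on log2 CPM with a prior count of 2, an assumed correlation of 0.01 and at least 5 tested members, and Benjamini-Hochberg adjustment over the 21 lists tested. Of these, 9 passed, 8 up and 1 down, and 0 passed with an estimated correlation. The test with an estimated correlation also raised p where the estimate lay below the assumed 0.01. For senescence and p53 targets (estimate 0.00813) the camera p went from 0.002816 to 0.03858. Other estimates were higher, up to 0.407 for glycolysis. A call lost in that test therefore does not by itself show that a list's members were correlated. Before the data were examined, 18 process lists, 13 marker lists, the tests, the alternatives and the rule for named genes were fixed. The rule takes genes with an adjusted p under 0.05, a mean of at least 1 CPM and groups that do not overlap, leaves out predicted genes, and names the 10 largest fitted rises and 10 largest falls. It adds up to 4 members of each process list by smallest p (2 where none pass) and Gata3, Rora, Il1rl1, Klrg1, Il5, Il13, Areg, Il10, Cdkn2a and Mki67. Other list members that are named were chosen after their values were seen, as exceptions to a list's direction, as markers of other cells or, for Il4, Il9, Slc2a1, Slc2a3, Dusp2, Cpt1a and S1pr1, as further changed genes. Some genes that the rule or the lists cover are not reported here, though they stay in the tests and the counts per list. Single measures per library were compared by a two-sided exact permutation test over 20 arrangements, whose smallest p is 0.1.

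On simulated counts with 200 changed genes among 11434 tested and the spread of these libraries, the edgeR test recovered 25.4% of genes changed 2-fold and 60.4% of those changed 4-fold, with 5.4% false calls. The alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, robust dispersion, a replicate block, stricter thresholds, an estimated list correlation, the fry rotation test, and leaving out each library. A per-library loess correction for transcript length and GC content (span 0.3) was added after seeing the data. For the gene lists, a change of direction under an alternative means a change in the direction of the camera or fry test, while the value given is the list's median log2 change.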

Results

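Group 2 innate lymphoid cells (ILC2) are tissue lymphocytes without antigen receptors that secrete type 2 cytokines such as IL-5 and IL-13. The series holds RNA-seq of ILC2 sorted from the brains of C57BL/6 mice, an inbred laboratory strain, and kept for 2 weeks in culture with IL-7, IL-2, IL-33 and stem cell factor. The young group came from mice of 2 to 3 months and the aged group from mice of 20 to 22 months, with 3 libraries in each group. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which can be technical. The deposited gene counts summed to 16477157, 20804291 and 17515659 in young libraries 1 to 3. They summed to 17314428, 17682940 and 17796301 in aged libraries 1 to 3. The single comparison the design names is aged against young, and it asks which genes differ in expression between the cultured cells of the 2 ages.

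Most tested genes of MHC class II presentation, of cytotoxic granules and of glycolysis were higher in cultured aged than in cultured young ILC2, with exceptions such as Gzmb, which fell, and none of these lists passed with an estimated correlation between genes. H2-Ab1, a chain of the class II molecule that presents peptides to CD4 T cells, rose from 60.2 ± 4.48 CPM in young to 1596 ± 287 CPM in aged libraries (mean ± SD, n = 3 each, scaled by TMM). Gzma, which encodes the protease granzyme A, rose from 53.3 ± 15.3 to 1978 ± 483 CPM. Klrg1, a receptor used as a marker of mature ILC2, fell from 86.6 ± 12.6 to 1.45 ± 2.12 CPM, and Il9 fell by 4.84 ± 0.57 (SE) on the log2 scale. The transcripts of Il13 and Areg, an IL-33-driven tissue repair factor, did not pass the test, with log2 changes of -0.10 ± 0.14 and 0.32 ± 0.12 (SE).

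Of 11805 genes tested, 2286 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 1325 were higher and 961 lower in aged libraries, and 730 and 728 of them by at least 2-fold. In 2268 of the changed genes the 3 libraries of each group did not overlap. Over all tested genes 38.2% had groups without overlap, where chance gives 10%. With library totals as the sole scaling the split turned to 717 higher and 2381 lower, and the median log2 change of the tested genes moved from -0.101 to -0.517, so directions here are relative to the TMM scaling. The 50 most abundant genes took 19.03 ± 0.908% of counts in young and 24.38 ± 0.400% in aged libraries (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

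**Figure D1:**
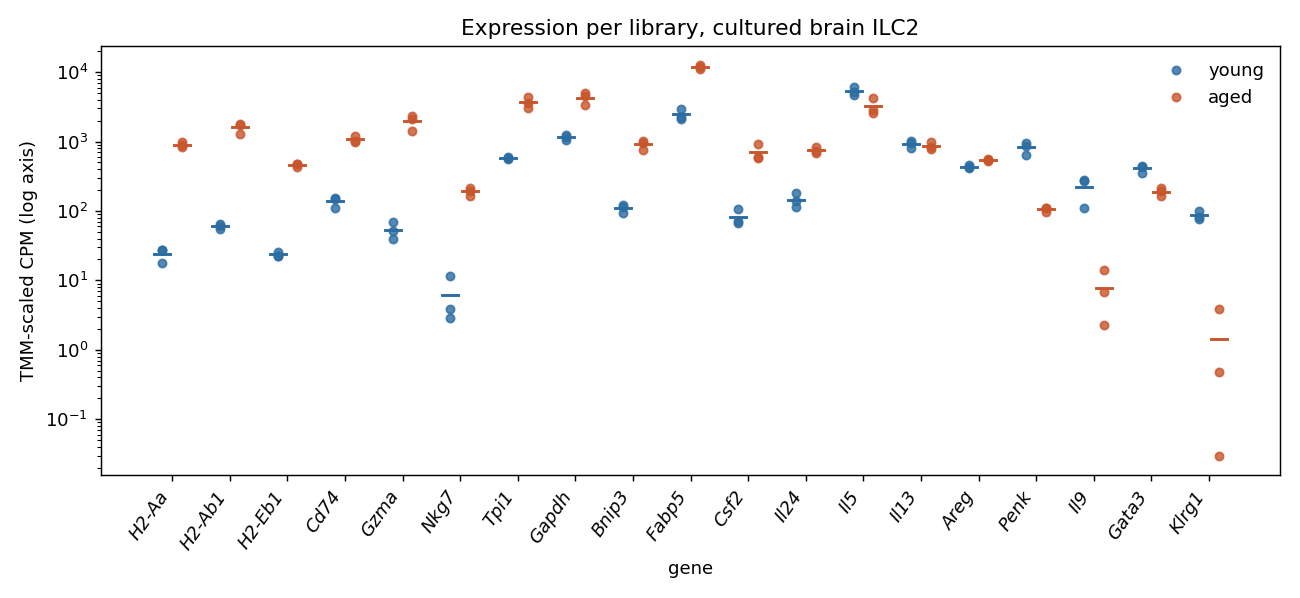
TMM-scaled CPM on a log axis for 19 genes of the fixed lists, with a point for each of the 3 young and 3 aged libraries and a bar at each group mean, where an aged library with 0 counts of Klrg1 is drawn near the bottom of the axis. H2-Ab1 has a mean of 60.2 CPM in young and 1596 CPM in aged libraries, while the Il13 libraries of the groups overlap.

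The log2 change also followed transcript length across genes. Its Spearman correlation with transcript length was -0.366 over 11703 genes, which are not independent replicates, and its correlation with GC content was 0.093. With genes ranked by length into 5 equal groups, 728 genes of the shortest group were higher and 80 lower in aged libraries, with a median log2 change of 0.511. In the longest group 55 were higher and 286 lower, with a median of -0.498. Ribosomal protein genes, which are short, took 6.04 ± 0.57% of counts in young and 7.93 ± 0.18% in aged libraries (SD, n = 3 each; two-sided exact permutation p = 0.1).

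**Figure D2:**
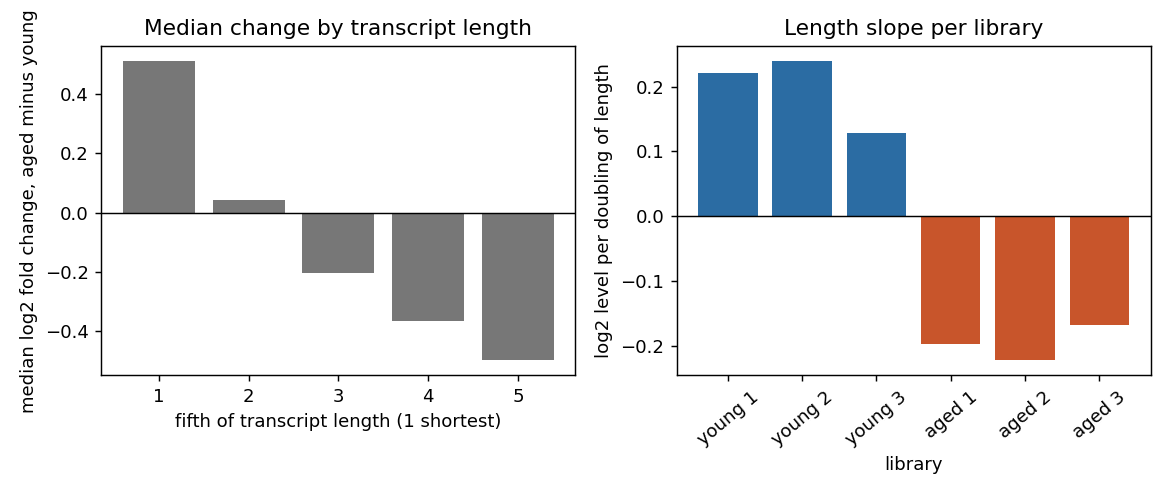
Left, the median log2 fold change (aged minus young) of tested genes in each of 5 equal groups by transcript length. Right, the log2 level gained per doubling of transcript length in each library, which ran from 0.129 to 0.24 in the young and from -0.223 to -0.169 in the aged libraries.

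MHC class II presentation genes rose as a group. Of 9 tested members, 6 rose and none fell, with the same counts when adjusted over the list alone, and the median log2 change was 2.84. H2-Aa on chromosome 17 (34282744 to 34287823, GRCm38) rose by 5.22 ± 0.20, H2-Ab1 (34257689 to 34269419) by 4.73 ± 0.17 and H2-Eb1 (34305867 to 34316674) by 4.29 ± 0.16 on the log2 scale (SE), each with an edgeR adjusted p of at most 1.54e-07. Cd74, the invariant chain that guides class II molecules through the cell, rose by 2.97 ± 0.16. Ciita, the activator of class II transcription, was low in both groups and did not pass the test, at 7.98 CPM in young and 6.69 CPM in aged libraries. The list passed limma's camera test (adjusted p = 5.344e-05). It did not hold with a correlation estimated from the data (adjusted p = 0.279 with an estimated correlation). Beside this rise, summed dendritic cell markers were at 84.8 ± 12.1 CPM of library totals in young and 281.7 ± 13.9 CPM in aged libraries (SD, n = 3 each), most of it from Batf3. Summed B cell markers were at 22.7 ± 4.65 and 49.3 ± 10.2 CPM, and summed microglial and macrophage markers at 63.5 ± 6.92 and 118.9 ± 19.8 CPM.

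Granzymes and other cytotoxic genes rose as a group, with 6 of 9 tested members higher, 1 lower and a median log2 change of 4.72, unchanged with Gzmd at its bound. The counts adjusted over the list alone were the same. Besides Gzma, Nkg7, a granule protein of killer lymphocytes, rose by 4.98 ± 0.47 and Gzme by 4.72 ± 0.52 on the log2 scale (SE). Gzmd had 0 counts in the young libraries and 34.7 ± 17.5 CPM (SD, n = 3) in the aged libraries, at least 733-fold higher against a floor of 3 counts over the young group. Gzmd and Gzme lie in a cluster of similar granzyme genes, and their counts are uncertain where reads were shared. Gzmb, by contrast, fell from 55.4 to 14.7 CPM. Camera gave the list an adjusted p of 0.0001396, and the adjusted p = 0.279 with an estimated correlation. Eomes, Tbx21 and Ncr1, which mark NK cells and ILC1, had 0 counts in the 6 libraries.

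Glycolytic genes rose together. Of 18 tested members 12 rose and none fell, or 14 and none adjusted over the list alone, with a median log2 change of 1.38. Tpi1 rose from 581.8 ± 10.9 to 3673 ± 630 CPM, Gapdh from 1145 ± 95.5 to 4305 ± 809 CPM and Aldoa from 1243 ± 158 to 4085 ± 325 CPM (SD, n = 3 each). Bnip3, a mitophagy gene induced by low oxygen, rose by 3.04 ± 0.17 on the log2 scale (SE; adjusted p = 1.65e-06, edgeR), with 22.3% of its exons overlapping a predicted gene on the opposite strand. The glucose carriers Slc2a1 and Slc2a3 rose by 1.62 and 1.82 on that scale. Hk1, Hk2 and Pfkp did not pass the test, with log2 changes of -0.69, 0.02 and 0.10. Gapdh and several of these enzymes have processed copies in the genome, so reads shared with them make the counts uncertain. In camera the list had an adjusted p of 3.57e-08, and the adjusted p = 0.32 with an estimated correlation.

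Respiratory chain genes shifted upward by less. Of 23 tested members 10 rose and 1 fell, or 12 and 2 adjusted over the list alone, with a median log2 change of 0.51. Cox5a, Cox6c, Cox7a2 and Ndufa1, subunit genes of complexes IV and I, rose by 0.99, 1.21, 1.05 and 1.20 on the log2 scale. Ndufs1, another subunit gene of complex I, fell by 1.54. The camera adjusted p was 0.01238, and the adjusted p = 0.32 with an estimated correlation. After a correction for transcript length and GC content, chosen after seeing the data, the list's median was -0.079 with an adjusted p of 0.837, and over all alternatives the adjusted p ran from 0.00557 to 0.837. With library totals as the sole scaling the median was 0.09 and the call was lost (adjusted p = 0.165). The calls of Cox5a, Cox7a2 and Ndufa1 were lost after the length and GC correction, with log2 changes of 0.19, 0.19 and 0.34.

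Type 2 and effector cytokines moved in both directions. Of 15 tested members 4 rose and 4 fell, or 5 and 4 adjusted over the list alone. Csf2, which encodes the growth factor GM-CSF, rose from 82.3 ± 21.9 to 701.2 ± 200.2 CPM and Il24 from 145.4 ± 35.5 to 748.1 ± 71.6 CPM. Penk, the precursor of enkephalin peptides, fell from 826.4 ± 162 to 105.8 ± 8.78 CPM, and Calca, the precursor of CGRP, from 59.4 ± 5.38 to 6.83 ± 2.85 CPM (SD, n = 3 each). Il5 stayed among the most abundant cytokine transcripts at 5335 ± 703 and 3230 ± 895 CPM and fell by 0.72 ± 0.18 on the log2 scale (SE; adjusted p = 0.0148, edgeR), with 27.1% of its exons overlapping an opposite-strand predicted gene. Il4 rose by 0.58. Il10 had a log2 change of 0.13 ± 0.23 and did not pass the test. The list did not pass the camera test (adjusted p = 0.974), whose direction was up beside a median log2 change of -0.18 and a mean of -0.25.

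Genes of ILC2 identity also split. Of 24 tested members 4 rose and 5 fell, or 4 and 6 adjusted over the list alone. Gata3, the transcription factor required for ILC2, fell from 412 ± 52.9 to 190.8 ± 24.0 CPM and Il1rl1, the IL-33 receptor chain, from 488.2 ± 43.2 to 276.1 ± 48.8 CPM, a fall that lost its call after the length and GC correction (log2 change of -0.34). Id2 rose from 3740 ± 607 to 6514 ± 206 CPM and Ly6a from 4903 ± 876 to 12252 ± 1216 CPM (SD, n = 3 each). Rora, another factor required for ILC2, had a log2 change of -0.05 ± 0.18 (SE) and did not pass. The camera adjusted p was 0.602. Of 21 genes for receptors and feedback of the culture cytokines, 1 rose and 4 fell, also adjusted over the list alone, and the camera adjusted p was 0.863. Stat5a and Stat5b, which relay IL-2 and IL-7 signals, fell by 1.45 and 1.15 on the log2 scale, and Il2ra fell by 0.42. After the length and GC correction the calls of Stat5b and Il2ra were lost, with log2 changes of -0.37 and 0.06.

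Inhibitory and costimulatory receptors included 7 genes that rose and 3 that fell of 15 tested, with the same counts adjusted over the list alone. Tnfrsf18 (GITR) rose from 409.9 ± 61.9 to 2296 ± 593 CPM and Tnfrsf4 (OX40) from 99.7 ± 6.71 to 501.6 ± 103 CPM (SD, n = 3 each). Cd28, a costimulatory receptor of T cells, rose by 4.20 ± 0.61 on the log2 scale (SE), while Icos fell by 1.32. The list did not pass camera (adjusted p = 0.105), but it did with library totals as the sole scaling (adjusted p = 0.031), and it passed the fry rotation test (0.002), within a range over all alternatives of 0.002 to 0.359. Exons of Tnfrsf18 overlapped an opposite-strand predicted gene over 27.2% of their length.

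**Figure D3:**
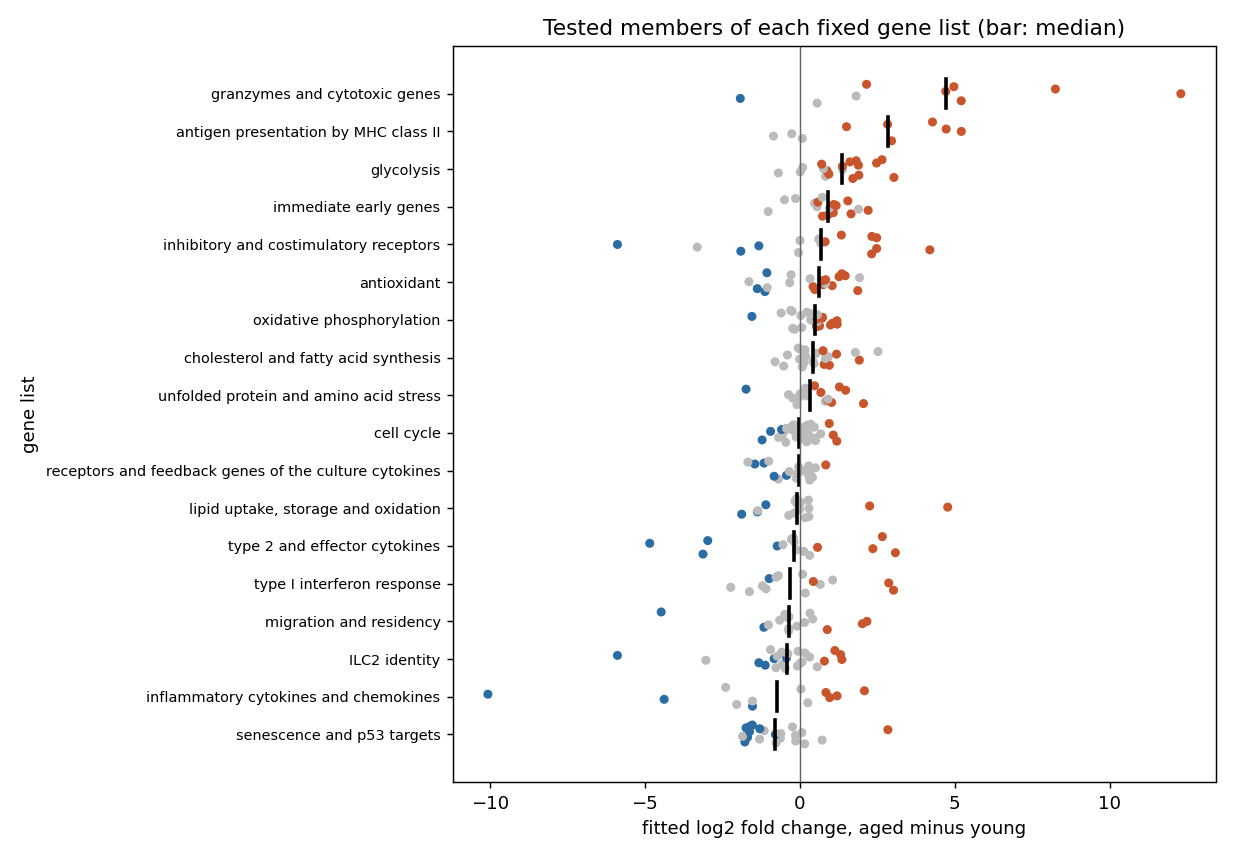
Fitted log2 fold changes (aged minus young) of the tested members of 18 gene lists, with a point per gene, coloured where the adjusted p was under 0.05 (orange higher, blue lower in aged), and a black bar at each median, where values of genes at 0 in a group depend on the prior count. The largest medians belong to granzymes and cytotoxic genes (4.72) and MHC class II genes (2.84), and the lowest to senescence and p53 targets (-0.78).

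Immediate early genes rose, with 9 of 17 tested members higher and none lower, or 11 and none adjusted over the list alone. Fos rose by 2.21 ± 0.24, Dusp2 by 1.66 ± 0.23 and Ier2 by 1.18 ± 0.15 on the log2 scale (SE). Jund rose by 1.56, but 52.6% of its exons overlap a predicted gene on the opposite strand. For this list the camera adjusted p was 8.204e-05, and the adjusted p = 0.32 with an estimated correlation. Among 18 genes of the unfolded protein and amino acid stress responses 7 rose and 1 fell, or 9 and 1 adjusted over the list alone. Atf4, a transcription factor of that response, rose by 1.03 and Sdf2l1 by 1.48, whereas Sesn2 fell by 1.73 (camera adjusted p = 0.01238, and adjusted p = 0.32 with an estimated correlation). With library totals as the sole scaling the call of this list was lost (median -0.0693, adjusted p = 0.0959), within a range of adjusted p over all alternatives of 0.00792 to 0.32.

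Antioxidant genes included 10 that rose and 3 that fell of 20 tested, or 12 and 5 adjusted over the list alone. Fth1, the ferritin heavy chain, rose from 2632 ± 267 to 9659 ± 1430 CPM (SD, n = 3 each), and Sod1, Sod2 and Txn1 rose by 1.27, 1.47 and 1.36 on the log2 scale. The members that fell included the glutathione synthesis gene Gclc, which fell by 1.37, and the catalase gene Cat, which fell by 1.12. Txnrd1, a thioredoxin reductase gene, fell by 1.06. The camera adjusted p was 0.04537, and the adjusted p = 0.32 with an estimated correlation. That estimate was -0.0147, below the assumed 0.01, so this loss does not show that the members were correlated. The call was lost without young library 1 (adjusted p = 0.073), young library 3 (0.0778), aged library 1 (0.0603), aged library 2 (0.0713) or aged library 3 (0.074), and after the length and GC correction (0.348). Cholesterol and fatty acid synthesis had 5 genes that rose and none that fell of 23, or 6 and none adjusted over the list alone (camera adjusted p = 0.01238, and adjusted p = 0.459 with an estimated correlation), and the list was lost without young library 3 (adjusted p = 0.0502). Fdps rose by 1.93 ± 0.17, with a same-strand predicted gene over 26.7% of its exons, and Msmo1 by 1.19 ± 0.20 on the log2 scale (SE).

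Lipid handling genes did not shift as a group (2 rose and 3 fell of 17, also adjusted over the list alone; camera adjusted p = 0.922, with a direction of down beside a median of -0.08 and a mean of 0.09). The fatty acid binding proteins Fabp5 and Fabp4 rose, Fabp5 from 2456 ± 440 to 11767 ± 764 CPM and Fabp4 from 5.67 ± 6.59 to 154.8 ± 23.5 CPM (SD, n = 3 each). The fatty acid oxidation genes Acadm and Hadha fell by 1.87 and 1.09 on the log2 scale, and Cpt1a fell by 1.36. Migration and residency genes had 3 that rose and 2 that fell of 17, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.863). Gpr183, a receptor for oxysterols, rose by 2.17, Cxcr4 by 2.02 and Ccr4 by 0.89, Ccr8 fell by 1.15, and S1pr1, a receptor for exit from tissue, fell from 18.4 ± 7.86 to 0.831 ± 1.44 CPM.

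Senescence and p53 target genes shifted downward, with 1 of 21 tested members higher and 8 lower, or 1 and 9 adjusted over the list alone. Phlda3, a p53 target, fell from 97.4 ± 1.29 to 31.8 ± 3.91 CPM and Ccng1 from 184.5 ± 46.3 to 54.17 ± 14.02 CPM (SD, n = 3 each). Cdkn2a, the p16 and p19 locus, had a log2 change of -1.29 ± 0.45 (SE) and did not pass (adjusted p = 0.0711, edgeR). By camera the list fell with an adjusted p of 0.01183, and the adjusted p = 0.279 with an estimated correlation. The estimated correlation was 0.00813, below the assumed 0.01, so the lost call does not show that the members were correlated. Of 32 cell cycle genes 3 rose and 3 fell, also adjusted over the list alone. Birc5, Cdk1 and Ube2c rose by 1.20, 1.09 and 0.96, Mcm6 fell by 0.58, and Mki67 had a log2 change of -0.42 ± 0.30 that did not pass. The camera adjusted p of the cell cycle list was 0.886, with a direction of up beside a median of -0.02 and a mean of -0.01, and it turned down with library totals as the sole scaling (median -0.443).

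Inflammatory cytokines and chemokines had 4 genes that rose and 3 that fell of 12 tested, also adjusted over the list alone. Mif rose from 804.5 ± 85.8 to 3427 ± 288 CPM and Cxcl3 from 675.5 ± 58.1 to 1560 ± 194 CPM (SD, n = 3 each), and Ltb rose by 0.85 on the log2 scale. Ifng had 7.33 ± 3.02 CPM in young and 0 counts in aged libraries, at least 112-fold lower in aged against a floor of 3 counts over the aged group, with a same-strand predicted gene over 25.9% of its exons. Type I interferon response genes had 3 that rose and 1 that fell of 14, also adjusted over the list alone. Isg20, Ifi27l2a and Ly6e rose by 2.87, 3.03 and 0.44 on the log2 scale. Neither list passed camera (adjusted p = 0.994 and 0.886), and in both its direction was up, beside medians of -0.74 and -0.30 and means of -1.37 and -0.01.

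The 10 largest rises by the fixed rule were genes with 0 counts in the young libraries. Mgarp, a mitochondrial protein gene, reached 80.9 ± 30.4 CPM (SD, n = 3) in aged libraries, at least 1708-fold higher against the floor of 3 counts over the young group. After Mgarp and Gzmd came Tmprss3, B3gnt8, Pmp22, Smtnl2, Tmem37, Lyz2, Ebf1 and Stfa3, at least 155-fold to at least 277-fold higher. The 10 largest falls were genes with 0 counts in the aged libraries. Dlk1, an imprinted gene of the Notch ligand family on chromosome 12 (109452823 to 109463336, GRCm38), had 27.7 ± 4.32 CPM in young libraries, at least 421-fold higher there against the floor over the aged group. It was followed by Cpe, a peptide hormone processing enzyme, at least 257-fold lower in aged libraries, and by Apoc4, Sdc2, Iigp1, Ccl24, Plcb1, Ppbp, Dcn and Ptger3, at least 164-fold to at least 213-fold lower.

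Many markers of other cell types had few or no counts, but others were expressed. The T cell genes Cd3e, Cd4, Cd5 and Cd8a, the B cell genes Cd79a and Ms4a1, and the macrophage genes C1qa and Csf1r had 0 counts in the 6 libraries. Other T cell genes had counts in both groups. In young and aged libraries Lat was at 19.9 and 21.6 CPM, Cd3g at 9.49 and 8.49 CPM, Cd247 at 10.3 and 6.38 CPM and Themis at 11.8 and 2.44 CPM. Lyz2, a lysozyme of myeloid cells, had 0 counts in young and 9.40 ± 2.88 CPM in aged libraries, and Tmem119, a microglial marker, rose from 0.673 to 51.1 CPM. Among microglial and macrophage markers 3 rose and 1 fell of 8 tested (camera adjusted p = 0.555). T cell markers had 1 that fell of 6 tested, Cd6 (camera adjusted p = 0.602). Mast cell and basophil markers had 0 that passed of 6 (camera adjusted p = 0.794, with a direction of down beside a median of 0.01 and a mean of -0.54), and 2 of them were abundant in both groups, Cyp11a1 at 1438 ± 30.8 and 1398 ± 114 CPM and Mcpt8 at 254.3 ± 23.6 and 265.7 ± 72.6 CPM (SD, n = 3 each). In the lists with fewer than 5 tested members, 2 of 3 B cell markers rose, as did 1 of 4 dendritic cell markers and 1 of 2 endothelial markers. Of 4 fibroblast markers 1 rose and 2 fell, or 2 and 2 adjusted over the list alone. The 3 tested ILC3 markers and the single tested markers of NK cells and ILC1, of choroid plexus and of neurons and glia did not pass, except that the choroid plexus marker Enpp2 passed adjusted over the list alone. Summed CPM of library totals in young and aged libraries was 331 and 224.5 for ILC3 markers, mostly Lta, 24.1 and 17.5 for fibroblast markers, 101.4 and 132.9 for endothelial markers, and 97.6 and 125.2 for choroid plexus markers, mostly Enpp2. For mast cell and basophil markers it was 1978 ± 40.7 and 1447 ± 55.1, and for T cell markers 64.4 ± 12.1 and 35.9 ± 6.97 (SD, n = 3 each). It was 33.6 and 15.9 for neuron and glia markers, 2.06 and 1.25 for NK cell and ILC1 markers, 0 and 0.0385 for neutrophil markers, and 0.0405 and 0.415 for red cell markers. These sums are not scaled by TMM, whose factors were 1.16 in young and 0.865 in aged libraries. On library totals, a gene with similar TMM-scaled CPM in both groups, such as Cyp11a1, therefore reads as lower in aged libraries.

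Leaving out young library 1 or young library 2 reduced the changed genes to 1314 and 1515, and the genes lower in aged to 399 and 480. The fall of Il5 lost its call without young library 1 (edgeR adjusted p = 0.0622), young library 3 (0.061), aged library 1 (0.0576) or aged library 2 (0.0666). Stat5b lost its call without young library 1 (0.0539) or young library 2 (0.0514). Ltb lost its call without young library 1 (0.0638) or aged library 2 (0.0536), and Cyp51 without young library 2 (0.0801), young library 3 (0.0537) or aged library 1 (0.0875). Hadha did so without young library 1 (0.0769), young library 2 (0.097) or aged library 2 (0.077). Ccr4 did so without young library 1 (0.062), young library 2 (0.0893), aged library 2 (0.0874) or aged library 3 (0.0922). Il2ra, Mcm6 and Ly6e each did so without young library 1 (0.155, 0.184 and 0.117), aged library 1 (0.0767, 0.097 and 0.119) or aged library 2 (0.106, 0.102 and 0.0922), Il2ra and Mcm6 also without young library 2 (0.0861 and 0.0612), and Ly6e also without young library 3 (0.0502). Calls were also lost with library totals as the sole scaling, where the log2 changes were 0.02 for Ly6e, 0.48 for Ccr4, 0.42 for Ltb, 0.55 for Cyp51 and 0.26 for Phgdh. After the length and GC correction they were -0.48 for Hadha, 0.11 for Ltb and -0.05 for Mcm6, which lost their calls. Of the 80 calls of named genes that kept their direction and passed after this correction, 11 shrank by more than 1.5 times on the log2 scale: Mif from 2.09 to 1.04, Jund from 1.56 to 1.02, Sdf2l1 from 1.48 to 0.81, Stat5a from -1.45 to -0.95, Ly6a from 1.32 to 0.77, Sod1 from 1.27 to 0.36, Cox6c from 1.21 to 0.54, Cxcl3 from 1.21 to 0.79, Ier2 from 1.18 to 0.70, Ier3 from 1.102 to 0.496 and Phgdh from 0.69 to 0.45. Il13, by contrast, passed as lower in aged libraries with library totals as the sole scaling (log2 change of -0.52, adjusted p = 0.0161) and after the length and GC correction (-0.62, adjusted p = 0.00656), within a range of adjusted p over all alternatives of 0.00656 to 0.992.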

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

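The length and GC correction was chosen after the data were seen, and the other alternatives were planned. The 2286 changed genes became 1171 at an adjusted p under 0.01 (831 higher, 340 lower) and 1458 at 2-fold or more (730 higher). With library totals alone 717 were higher and 2381 lower. Leaving out 1 library gave 1314 to 2141 changed genes, with 915 to 1344 higher and 399 to 849 lower. DESeq2 called 3070 and the length and GC correction 1891, of which 1360 were shared with the 2286 and 1350 had the same direction. Of 9 shifted lists 0 remained with an estimated correlation. Lists with an estimate below the assumed 0.01 were lost too, so these losses alone do not show correlated members. The fry test called 12 lists, gaining ILC2 identity, type I interferon, inhibitory and costimulatory receptors and microglia, and losing cholesterol synthesis. The replicate numbers are not stated to pair the samples, and deviations of same-numbered samples correlated at 0.02, 0.009 and 0.041, although 5 of 6 samples correlated best with their own number. A replicate block gave 2008 changed genes (1208 higher, 800 lower) and 8 lists, and lost Hadha, Il2ra, Mcm6 and the antioxidant list. Directions turned, for results that had not passed except Il2ra and oxidative phosphorylation, as follows. With library totals alone the log2 change of Areg was -0.0941, that of Il10 -0.28 and the cell cycle median -0.443. With the length and GC correction it was 0.0588 for Il2ra, 0.35 for Mki67 and 0.64 for Rora, which then passed. List medians there were -0.055 for type 2 cytokines, 0.0922 for culture cytokine receptors, -1.34 for inflammatory cytokines, -0.28 for type I interferon, -0.0789 for oxidative phosphorylation and 0.11 for migration. Test directions turned under fry for type 2 cytokines (-0.18) and inflammatory cytokines (-0.74), and under the block for these lists (-0.133 and -0.734) and lipid handling (-0.0705). Without 1 library values ran from -0.0446 to 0.332 for Il10, -0.20 to 0.0038 for Il13 and -0.17 to 0.0599 for Rora. List medians ran from -0.147 to -0.0412 for type 2 cytokines, -0.132 to 0.0252 for cell cycle, -1.62 to -0.19 for inflammatory cytokines, -0.74 to -0.15 for type I interferon, -0.16 to 0.0319 for lipid handling and -0.0549 to 0.0774 for mast cells and basophils. The cause was not tested. Areg passed with DESeq2, and Cdkn2a with DESeq2, library totals alone and the length and GC correction. At this spread 25.4% of simulated 2-fold and 60.4% of 4-fold changes were recovered. Far fewer genes changed in the simulation than the 2286 called here, so these rates may not carry over. A missing call is better read from the gene's own log2 change and SE, together with its values under the alternatives. Main values were -0.10 ± 0.14 for Il13, -0.05 ± 0.18 for Rora, 0.32 ± 0.12 for Areg and 0.13 ± 0.23 for Il10. With the main settings these lay several SE from a 2-fold change. The SE covers the spread between libraries, not the choice of scaling or correction. After the length and GC correction the log2 change was -0.62 for Il13 and 0.64 for Rora, so the SE alone does not exclude a 2-fold change. The values of Mki67 (-0.42 ± 0.30) and Cdkn2a (-1.29 ± 0.45) left a 2-fold change open.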

Other observations

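The per-type marker tests for B cells, dendritic cells and microglia or macrophages were chosen only after the summed marker result was seen. The length and GC correction, the count of genes absent in an age group and the genes named in the next paragraph were chosen after seeing the data too, and the other tests here were set before their results were seen.

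Some genes had 0 counts in an age group. With 0 counts in the 3 libraries of a group and at least 5 CPM of library totals in each library of the other, 6 genes were absent in young and 13 in aged libraries, and no other split of the 6 libraries gave any. The genes named next are not among these, as they had counts in both groups. Peg10, an imprinted gene derived from a retrotransposon, fell from 64.9 ± 9.66 to 0.955 ± 0.513 CPM (SD, n = 3 each). Ascl2 rose from 0.149 ± 0.259 to 35.6 ± 7.21 CPM. Csn2, a milk casein, fell from 1769 ± 355 to 461 ± 17.7 CPM, Pth, the parathyroid hormone gene, from 185.6 ± 36.1 to 21.6 ± 8.86 CPM, and Nts, the neurotensin gene, from 79.6 ± 19.4 to 11.1 ± 3.25 CPM. A fall of imprinted genes as a class was a hypothesis. Of 24 other imprinted genes listed, 10 were tested, with a median log2 change of 0.14. Of these 3 rose, among them Ascl2, which is imprinted too and counts toward this median, and 1 fell. A fall of peptide hormone genes as a class was another hypothesis. Of 24 other such genes listed, 8 were tested, with a median of 0.09, 0 that rose and 2 that fell. Both medians lay slightly above 0, on the side set beforehand as against a fall of the whole class. Most listed genes of each set were not tested, and members fell in each set, 1 imprinted gene and 2 peptide hormone genes. A fall of a class or of part of it is therefore not decided.

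The comparison of ages gave 2286 changed genes in the real split, and the highest of the other splits gave 0. As 1 of 10 splits, the real split cannot reach a share under 0.05.

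Glycolysis genes were higher in aged libraries. The tables argue against the length and GC trend as the whole cause, since the list's median log2 change was 1.27 after correction. A low-oxygen response is a candidate explanation. Of 20 hypoxia-induced genes outside the list, among them Rora, which the ILC2 identity list also holds, 19 were tested, 12 rose and 0 fell, with a median of 1.96 (camera p = 5.1e-09, and p = 0.0168 with an estimated correlation). Whether age or culture conditions would bring it was untested, and the design does not separate them.

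MHC class II genes were higher in aged libraries, and a median log2 change of 2.43 after correction argues against the length and GC trend as the whole cause. The increase of summed B cell, dendritic cell and macrophage markers came to 21.3% of that of H2-Ab1, from 171 ± 12.3 to 449.9 ± 22.1 CPM of library totals (SD, n = 3 each), above the 10% set beforehand for carry-over of such cells, and to 6.33% without Batf3. Batf3 was at 67.5 CPM in young libraries already and at 316.9 CPM in aged libraries, a smaller change than that of H2-Ab1, from 60.2 to 1596 CPM. The other dendritic cell markers were low in aged libraries, with 0 counts of Clec9a, Cd209a and Siglech, 1 count of Itgax, and 0.852 CPM of Zbtb46, 2.10 CPM of Flt3 and 6.19 CPM of Xcr1. The median marker in aged libraries was at 0.000699% of the level of H2-Ab1 for B cells (4 of 8 markers at 0 counts), 0.0274% for dendritic cells (3 of 8) and 0% for microglia or macrophages (8 of 15), which argues against carry-over of B cells, dendritic cells, microglia or macrophages as the whole cause. By another criterion, at least 50% of a type's markers at 0 counts, dendritic cells would not be excluded. Cd79b at 44.6 CPM and the microglial marker Tmem119 at 51.1 CPM were exceptions beside Batf3. Since the summed markers passed the share set beforehand, a part from such cells stays open, as do a change with age and a change in culture. The labels name a sort on ILC2 surface markers before culture but not which markers, and a gate on them would remove most such cells only if it excluded their lineages.

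Short transcripts were higher and long transcripts lower in aged libraries. Without 311 ribosomal, respiratory and proteasome genes the rank correlation across genes was -0.35, which argues against those families alone. The length slopes of the groups were separated by a gap of 0.297, with means of 0.196 ± 0.06 in young and -0.196 ± 0.027 in aged libraries (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). RNA integrity or library preparation that differed between the groups cannot be told apart from age, because each group holds a single age and no difference in batch between the libraries is given in the sources used here. The column names of the 6 libraries share a date-like tag, and the step it refers to is not stated.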
